A study of Homo sapiens with 8 samples.

How the data were processed

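Total RNA from elutriated human monocytes was labelled with biotin and hybridised to one-colour oligonucleotide arrays of 54675 probe sets, per the labels' protocols. The deposited values are intensity values on a linear scale, namely MAS5 signals, 1 per probe set and array, per the submitters' processing notes; the MAS5 version, the detection calls and any filter are not given in the sources used here. The values show that the authors scaled the arrays: the mean after trimming 2% of probe sets at each end was 100 on every array and differed between arrays by at most 0.00128%. Since this lay within the 5% set in advance, the values were used without further scaling. No genome build is named in the sources used here, so no coordinates are given.

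Of the probe sets, 62 were array controls and 288 were left out because their genes (XIST, Y-linked, HLA, immunoglobulin and T cell receptor genes and a few commonly deleted genes) can tell about a person. Probe sets were named from the platform annotation, in which 41097 had 1 gene symbol, 1801 several and 11777 none; the symbols of 41043 were updated through Entrez gene identifiers, and those with several or none stayed unnamed. List members without a probe set named there were not analysed here. A value of 16 was added to each signal before taking log2, and the lowest 40% of probe sets by mean log2 value over all 8 arrays were not tested, which put the limit at a mean signal of about 11.3 and left 32595. All fold changes are on this log2(signal + 16) scale, which understates the change of dim genes. A gene was read at the probe set with the highest mean over all arrays, giving 13771 genes, and disagreement with its other probe sets is stated with the result.

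LTD4 was compared with vehicle in limma 3.58.1 (R 4.3.3) with donor and treatment as terms, a variance prior that follows signal, two-sided tests and Benjamini-Hochberg adjustment over all probe sets, at an adjusted p of 0.05. The donor is a block because the labels number the 4 donors and give each 1 sample per arm. The pairing also showed in the data: deviations from the group means correlated at 0.303 to 0.511 across probe sets within a donor and at most at 0.0360 between donors, and 4 of 4 donors had their best match in their own pair. Part of this gap is built in, since taking off a mean over 4 samples lowers the correlations between donors. Without the donor block 0 probe sets passed. Donors are separate people, so the errors hold the spread between donors in the change. The fit had 9.04 degrees of freedom, 3 from the samples and the rest from the prior. For arrays, precision is limited by their number.

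A set of 19 gene lists, fixed before the data were examined together with the tests, alternatives and naming rule, was tested with limma's camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated and with fry. Counts are given over all probe sets and adjusted over the list alone. The naming rule took genes past the threshold in 4 of 4 donors, filled up to 20 genes by smallest unadjusted p, then CYSLTR1 and CYSLTR2, and up to 4 members of highest mean log2 value of a list where none passed. Of these examples 1 per list is given, and none for the B cell list, where the SD exceeded the mean. Genes that passed over their list alone were added after the values were seen. RNA quality was compared by exact permutation of signs within donors.

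The procedure was tested on simulated data for LTD4 against vehicle with 32595 probe sets and the arrays' own means and spread. It recovered 18% of 50 probe sets changed by 0.5 on the log2 scale, 84% of 50 changed by 1, and 100% of 50 each changed by 2 and 3, with 10 unchanged probe sets among 161 calls. The real arrays gave 2 calls, and with more calls the Benjamini-Hochberg adjustment lets larger unadjusted p through. These shares thus overstate what the fit could recover on the real arrays. Camera called a list of 30 probe sets shifted by 0.3 and 0 of 19 unshifted lists. The simulated errors were drawn independently for each probe set. This run thus cannot show how often camera calls unshifted lists whose members vary together, such as ribosomal proteins (estimated correlation 0.80). Alternatives covered the donor block, quantile normalization and median centring, a pseudocount of 1 or 64, no filter or a filter on the lowest 60%, the variance prior, the mean of a gene's probe sets, the threshold, the set test, and leaving out each donor.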

Results

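Leukotriene D4 (LTD4) is a lipid mediator made from arachidonic acid that acts on the G protein-coupled receptors CYSLTR1 and CYSLTR2. Gene expression was measured in human monocytes isolated by elutriation, which separates cells by size and density. Monocytes of 4 donors were kept in culture overnight and then given either 100 nM LTD4 or the ethanol vehicle for 30 min, so each donor gave 1 sample to each arm and the series holds 8 arrays. The arrays had a common scale: the mean signal after trimming 2% of the probe sets at each end was 100 on every array, and the median signal ran from 18.0 to 20.6. The log2 values of any 2 arrays correlated at 0.954 to 0.982 across probe sets, and 0 pairs of arrays held identical values. The comparison of LTD4 with vehicle asks which transcripts differ after 30 min; the study's title names a role of CYSLTR1, which this comparison does not test, since no sample used here had that receptor blocked.

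FOSB, a member of the AP-1 family of transcription factors, rose from a mean signal of 24.1 ± 14 with vehicle to 226 ± 119 with LTD4 (SD, n = 4 donors), a log2 change of 2.49 (SE 0.22, 95% interval 1.98 to 3.00, limma adjusted p = 0.0463), and was higher in 4 of 4 donors. ATF3, a stress-inducible transcription factor of the ATF/CREB family, rose at its less bright probe set, from 101 ± 20.3 to 253 ± 37.8 (log2 change 1.21, SE 0.12, limma adjusted p = 0.0463, higher in 4 of 4 donors). These were the 2 probe sets of 32595 tested that passed limma's adjusted p of 0.05. No lower probe set passed (0), though with donor as a random block limma called 1, of TMEM120B (adjusted p = 0.0410), and at an unadjusted p under 0.05 limma found 1025 lower and 1114 higher probe sets, against 1630 expected by chance in all. Read at 1 probe set per gene, 1 gene of 13771 passed, FOSB. At a limma adjusted p under 0.1, 8 probe sets and 6 genes passed, all higher with LTD4. The vehicle level of FOSB was little above the array medians of 18.0 to 20.6, near background, and its log2 change was 3.13 with a pseudocount of 1 and 1.63 with 64, so its size depends on that setting. The FOSB call was lost without replicate 3 (limma adjusted p = 0.214), without replicate 4 (0.271), without the donor block (0.345, where 0 probe sets passed and 915 had an unadjusted p under 0.05), with a pseudocount of 1 (0.0676), without a filter (0.175), with the lowest 60% not tested (0.0725) and without a trend in the variance prior (0.787). The ATF3 probe set lost its call under each of these settings, with quantile normalization (limma adjusted p = 0.0582) and without replicate 2 (0.230), 9 of 14 alternatives in all, with a log2 change of 0.94 to 1.33 over the 14. Over 15 alternatives the limma adjusted p of FOSB ran from 0.00483 to 0.787, and over 14 that of the ATF3 probe set ran from 0.0203 to 0.787. Without replicate 1, 9 genes passed, all higher.

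**Figure D1:**
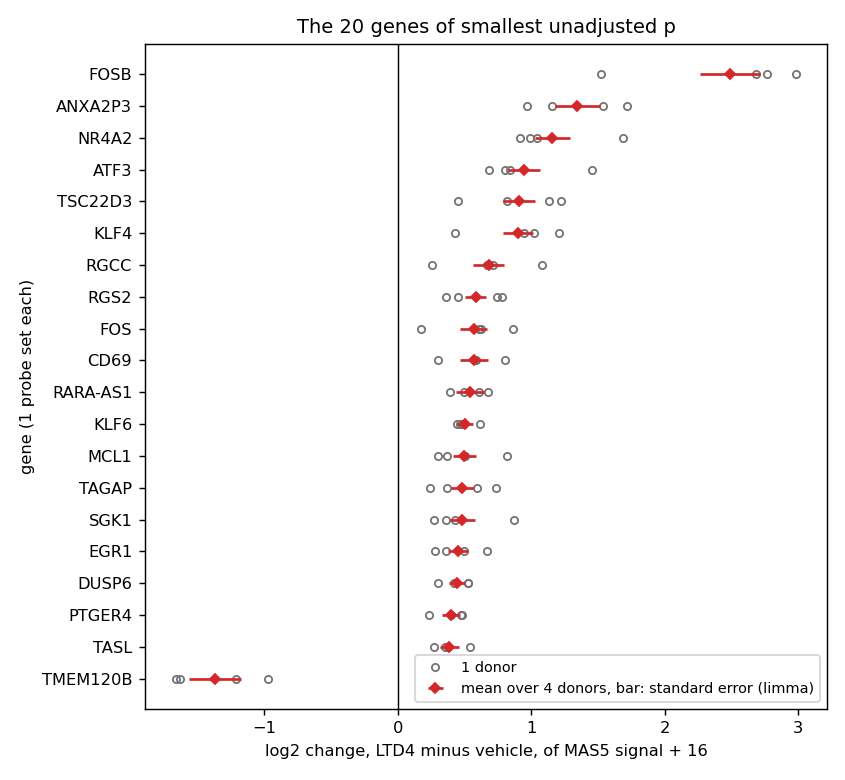
Log2 change of MAS5 signal + 16, LTD4 minus vehicle, in each of the 4 donors (open circles) for the 20 genes of smallest unadjusted p, with the mean over donors (diamonds) and its standard error from limma (bars). FOSB has the largest mean change, 2.49, and TMEM120B, at -1.37, is the 1 gene of the 20 below 0.

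The other 5 genes with a limma adjusted p under 0.1 did not pass 0.05, and each had an adjusted p of 0.0994. NR4A2, an orphan nuclear receptor induced as an early response gene, had mean signals of 196 ± 72.8 with vehicle and 438 ± 86.3 with LTD4 (log2 change 1.16, SE 0.13), and its other tested probe sets gave 1.10 and 1.06. ATF3 at its brightest probe set had 574 ± 119 and 1116 ± 194 (log2 change 0.95, SE 0.12). KLF4 and KLF6, zinc finger transcription factors of the Krüppel-like family, had log2 changes of 0.90 (SE 0.11) and 0.50 (SE 0.06), KLF6 from 1586 ± 141 to 2254 ± 160. The other probe sets of KLF6 gave 0.78, 0.47, 0.21 and 0.14, the 0.21 at one about as bright (unadjusted p = 0.194), and that of KLF4 gave 0.73. ANXA2P3, an annexin A2 pseudogene, had a log2 change of 1.35 (SE 0.17) from 31.2 ± 21.3 to 101 ± 44.1, and 0.78 with a pseudocount of 64. Its assignment is uncertain because the probe set can share sequence with near-identical annexin A2 transcripts.

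The list of immediate early transcription factors, genes switched on within minutes of a stimulus, had 30 members tested, of which 1, FOSB, passed over all probe sets. Adjusted over the list alone, 17 members passed, 15 higher and 2 lower with LTD4. The higher ones included EGR1 (log2 change 0.45, 2290 ± 706 to 3184 ± 1087), FOS (0.57, 1676 ± 480 to 2556 ± 909), EGR3 (0.97) and NR4A1 (0.73), beside FOSB, NR4A2, ATF3, KLF4 and KLF6, and the rest were MAFF, CEBPD, KLF10, IER2, BHLHE40 and JUND, at 0.17 to 0.31. The lower ones were JUN, an AP-1 subunit (-0.30, SE 0.11), and CEBPB (-0.18, SE 0.06), both lower in 4 of 4 donors. Without replicate 3 the change of JUN was -0.15, and after quantile normalization that of CEBPB was -0.28 and that of JUND 0.11. Other probe sets of EGR1 gave 0.22 and 0.50. JUN's other tested probe sets gave -0.42, -0.08 and 0.02, the dimmer probe sets of NR4A1 gave 0.30 and 0.05, that of BHLHE40 gave 0.01, and those of JUND gave 0.20, 0.14 and -0.17. The list's median log2 change was 0.19 and its mean 0.33, and camera placed it above other genes (limma adjusted p = 2.34e-13). That call was lost in camera with an estimated correlation (limma adjusted p = 0.169 with an estimated correlation). Fry did not call the list (limma adjusted p = 0.0766).

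Among 22 genes of MAP kinase and receptor signalling feedback, 0 passed over all probe sets in limma and 9 had an unadjusted p under 0.05, 8 higher and 1 lower. Adjusted over the list alone, 7 passed, all higher. RGS2, a GTPase-activating protein for Gq-coupled receptor signalling, had 2771 ± 582 with vehicle and 4210 ± 1093 with LTD4 (log2 change 0.58, SE 0.08, limma adjusted p over all probe sets = 0.138), and DUSP6, a phosphatase of ERK, had 2499 ± 969 and 3456 ± 1518 (0.45, SE 0.06, limma adjusted p = 0.142). The others were RASGEF1B (0.72), PHLDA1 (0.53), TRIB1 (0.48), SGK1 (0.48) and DUSP1 (0.29), each higher in 4 of 4 donors. RASGEF1B was dim (32.5 ± 9.50 with vehicle and 64.8 ± 22.4 with LTD4), and its log2 change ran from 0.41 to 0.96 over 15 alternatives. Other probe sets gave 0.26 and 0.45 for DUSP6, 0.18 to 0.93 for PHLDA1, 0.70 for TRIB1 and 0.58 and 0.95 for DUSP1. The list's median was 0.18, and 0.30 with a pseudocount of 1, and camera placed it above other genes (limma adjusted p = 1.00e-05). With an estimated correlation camera did not (limma adjusted p = 0.169 with an estimated correlation). The estimate, -0.036, lay below the preset 0.01, so a higher correlation between members does not explain the loss. Estimating the correlation also bases camera's p on the 3 degrees of freedom from the samples, which the preset correlation does not. With so few, the same statistic gives a larger p. How far this accounts for the loss was not tested. Fry, which tests whether the list's genes move 1 way on balance and compares them with no other genes, passed upward (limma adjusted p = 0.0294).

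Genes outside these lists were also among the 20 of smallest p, and none of them passed 0.05 over all probe sets. TSC22D3, a glucocorticoid-induced leucine zipper protein, had 847 ± 133 with vehicle and 1596 ± 203 with LTD4 (log2 change 0.91, SE 0.12, limma adjusted p = 0.109). RGCC, TAGAP and TASL had log2 changes of 0.68, 0.48 and 0.39, and the other probe sets of TAGAP gave 0.77, 0.46, 0.38 and -0.06. RARA-AS1, an antisense transcript of the RARA locus, had 0.54 and is uncertain as any antisense assignment is here. TMEM120B was the 1 gene of the 20 with a lower signal, 48.7 ± 11.9 with vehicle and 8.99 ± 4.07 with LTD4 (log2 change -1.37, SE 0.19, limma adjusted p = 0.161), and its other probe set, near background, gave 0.15. The LTD4 level also lay near background, below the limit of about 11.3 for tested probe sets, so the size of this change is uncertain. With donor as a random block it passed (limma adjusted p = 0.0410), and over 14 alternatives its adjusted p ran from 0.0410 to 0.824 and its log2 change from -2.37 to -0.61. Across 12 of the 20 genes, 25 other probe sets were tested; 23 had the same direction as the gene's value, 19 of them with an unadjusted p under 0.05, and 2 had the opposite direction.

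**Figure D2:**
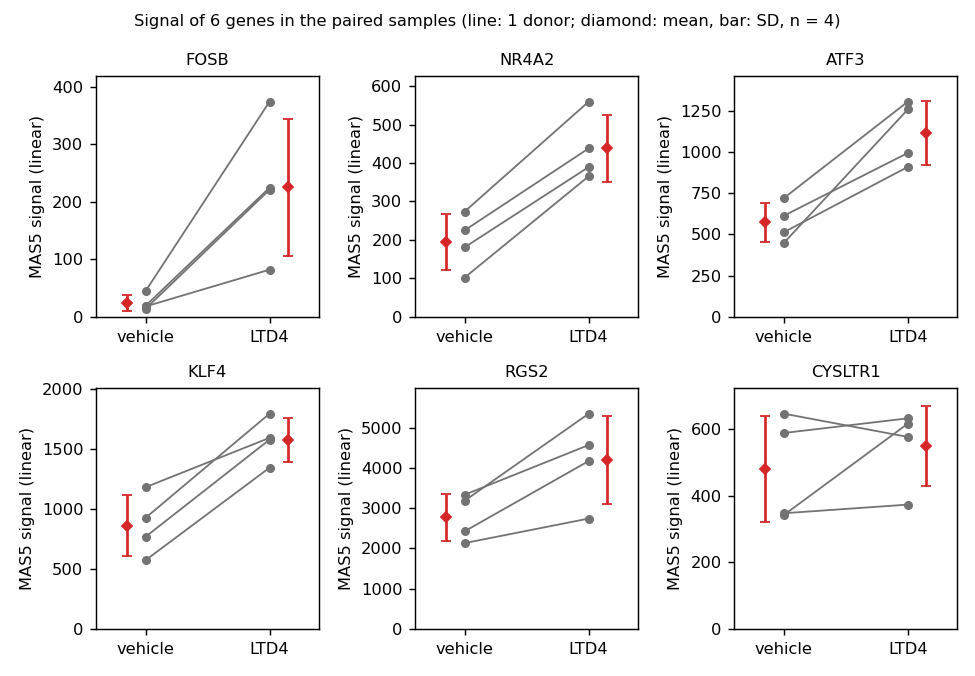
MAS5 signal on a linear axis starting at 0 in the vehicle and LTD4 samples of FOSB, NR4A2, ATF3, KLF4, RGS2 and CYSLTR1, with 1 line per donor and the mean (diamonds) with SD (bars, n = 4). FOSB goes from a mean of 24.1 to 226 and CYSLTR1 from 481 to 550, with CYSLTR1 higher in 3 of 4 donors.

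For both receptors of LTD4 the interval of the change included 0. CYSLTR1 had 481 ± 159 with vehicle and 550 ± 120 with LTD4 (log2 change 0.22, 95% interval -0.10 to 0.54, limma adjusted p = 0.778), and its other tested probe sets gave 0.15 and -0.28. The CYSLTR1 value rested mostly on replicate 1, without which it was 0.01 (limma adjusted p = 0.986), and without replicate 3 it was 0.34. CYSLTR2 was near background at 15.7 ± 7.49 and 13.7 ± 1.65 (log2 change -0.06, 95% interval -0.57 to 0.46, limma adjusted p = 0.967). Of 23 tested members of the leukotriene and eicosanoid pathway, 0 passed over all probe sets in limma and 5 had an unadjusted p under 0.05. Adjusted over the list alone, 2 passed, both receptors of prostaglandin E2: PTGER4 (0.40, 1457 ± 248 to 1917 ± 260) and PTGER2 (0.37, 475 ± 106 to 614 ± 95.4). ALOX5, the 5-lipoxygenase that starts leukotriene synthesis, had a log2 change of 0.03. The list's camera test missed the threshold (limma adjusted p = 0.0505; adjusted p = 0.290 with an estimated correlation), with a median of 0.03. Without replicate 4 it passed at the preset correlation (limma adjusted p = 0.0279, median 0.06; adjusted p = 0.554 with an estimated correlation), and over its alternatives the adjusted p ran from 0.0279 to 0.554.

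Of 18 tested members of the calcium, NFAT and CREB responsive list, 1 passed over all probe sets, FOSB, and 5 passed adjusted over the list alone, all higher. These were FOSB, NR4A2, EGR3 and NR4A1, which the immediate early list also holds, and CD69, a lymphoid and myeloid activation antigen (0.57, SE 0.11, 210 ± 120 to 319 ± 181). The median was 0.02 and the mean 0.32, and camera placed the list above other genes (limma adjusted p = 0.00285). With an estimated correlation it did not (limma adjusted p = 0.169 with an estimated correlation). The estimate was -0.019, also below the preset 0.01. Fry passed upward (limma adjusted p = 0.0494). Without replicate 1 the median was -0.02 while camera still placed the list higher at the preset correlation (limma adjusted p = 0.00231; adjusted p = 0.320 with an estimated correlation).

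In the RNA decay and antiproliferative list, 0 of 19 tested genes passed over all probe sets in limma and 5 had an unadjusted p under 0.05, and 3 passed adjusted over the list alone, all higher: MCL1, an anti-apoptotic protein (0.50, SE 0.08, and 0.07 to 1.26 at its other probe sets), PPP1R15A (0.46) and ZFP36, which promotes decay of cytokine mRNAs (0.31). This list's median was -0.01 while its mean, 0.04, and its camera test pointed up (limma adjusted p = 0.425). Among 17 chemokines, 0 passed over all probe sets in limma and 2 had an unadjusted p under 0.05; 1, CCL2, passed adjusted over the list alone (log2 change 0.51, SE 0.11, 535 ± 435 to 704 ± 517, higher in 4 of 4 donors). Of 23 cytokines and growth factors and 22 NF-kappaB targets, 0 passed over all probe sets in limma or adjusted over the list alone, and 3 and 2 had an unadjusted p under 0.05. TNFSF13B and CD44, the brightest of each by mean log2 value, had log2 changes of 0.08 and 0.10, CD44 -0.03 after quantile normalization. Camera called none of the chemokine, cytokine and NF-kappaB lists (limma adjusted p = 0.363, 0.425 and 0.425), though without replicate 1 it called each of them higher at the preset correlation (limma adjusted p = 0.0374, 0.0398 and 0.000204). Those calls were lost with the correlation estimated (limma adjusted p = 0.456, 0.438 and 0.298 with an estimated correlation). The genes of this and the preceding lists that passed over their list alone but are not among the 20 of smallest p were chosen after their values were seen.

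**Figure D3:**
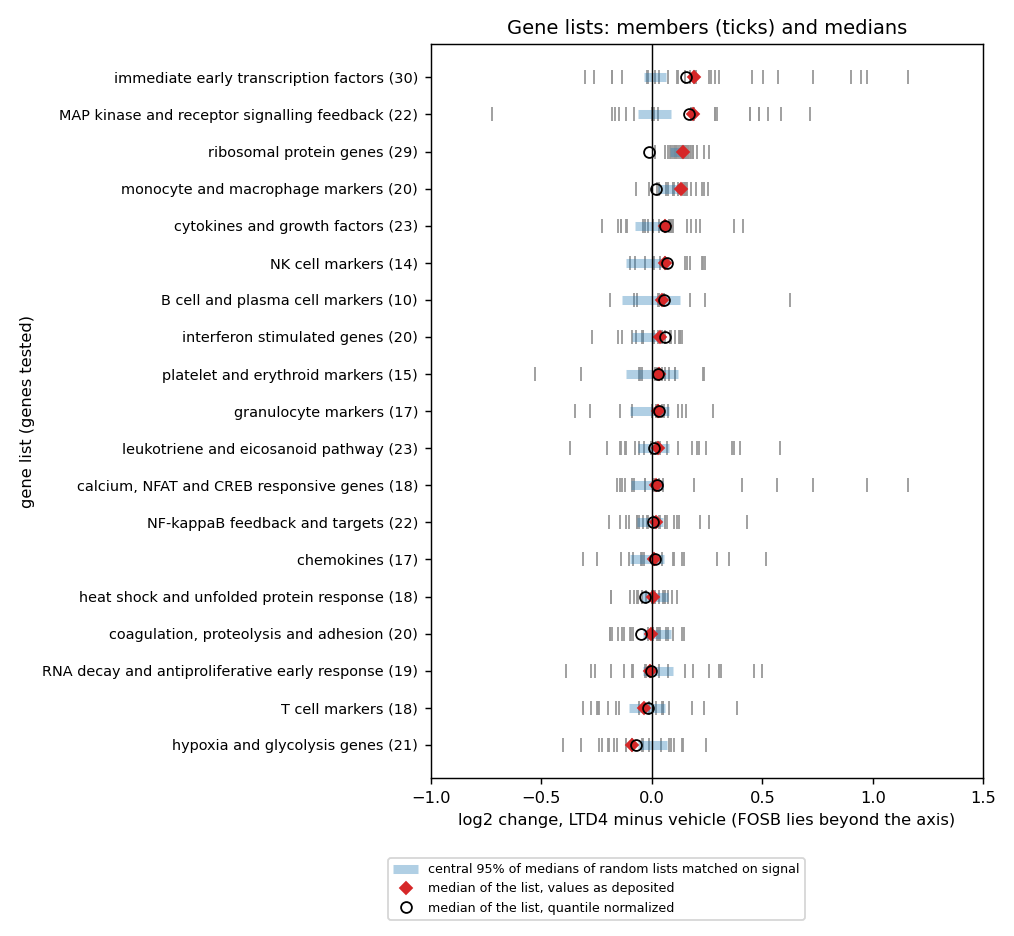
Log2 change, LTD4 minus vehicle, of the tested members of 19 gene lists (ticks), with the list median for values as deposited (diamonds) and after quantile normalization (circles), and the central 95% of medians of 10000 random lists matched on signal (bars). The immediate early and feedback lists have medians of 0.19 and 0.18, and the ribosomal protein median goes from 0.14 to -0.01 with quantile normalization.

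All 29 tested ribosomal protein genes had a higher mean with LTD4 in the values as deposited, but 0 passed over all probe sets in limma or adjusted over the list alone, and 17 had an unadjusted p under 0.05. RPS16 had a log2 change of 0.14 (8831 ± 1099 to 9734 ± 1333), and -0.04 after quantile normalization. The list's median was 0.14 and camera placed it above other genes (limma adjusted p = 1.53e-16; adjusted p = 0.437 with an estimated correlation). After quantile normalization the median was -0.01 (limma adjusted p = 0.946). Among 20 monocyte and macrophage markers, 0 passed over all probe sets in limma, 6 had an unadjusted p under 0.05 and 1, CD14, the lipopolysaccharide co-receptor, passed adjusted over the list alone (0.24, SE 0.06, 6887 ± 997 to 8189 ± 1643), though after quantile normalization its change was 0.05. That list's median was 0.13, and camera placed it above other genes (limma adjusted p = 3.11e-07; adjusted p = 0.169 with an estimated correlation), and after quantile normalization its median was 0.02 (limma adjusted p = 0.319).

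The remaining pathway lists had 0 members past the threshold in limma over all probe sets or adjusted over the list alone. Among 20 coagulation, proteolysis and adhesion genes, 1 had an unadjusted p under 0.05, FN1, fibronectin (log2 change 0.14, and -0.02 after quantile normalization). That list's median was -0.01 and its mean -0.03, while camera pointed up (limma adjusted p = 0.970). Interferon stimulated genes (20 tested, 0 with an unadjusted p under 0.05) had a median of 0.04 (limma adjusted p = 0.591), and ISG15 had 485 ± 149 with vehicle and 618 ± 467 with LTD4. At the preset correlation camera called the list higher without replicate 1 (median 0.13, limma adjusted p = 0.00611) and lower without replicate 2 (median -0.23, limma adjusted p = 1.43e-06). Both calls were lost with the correlation estimated (limma adjusted p = 0.660 and 0.336 with an estimated correlation). Heat shock and unfolded protein response genes (18 tested, 0 with an unadjusted p under 0.05) had a median of 0.01 and a mean of -0.01, and camera pointed down (limma adjusted p = 0.832). HSP90AA1 had a log2 change of 0.00 (SE 0.07), and its other probe sets gave 0.06, 0.12 and -0.09. Of 21 hypoxia and glycolysis genes, 4 were lower and 1 higher at an unadjusted p under 0.05, the median was -0.09 and camera did not call the list (limma adjusted p = 0.164), while after quantile normalization it called it lower (limma adjusted p = 0.0290, median -0.07), a call lost with the correlation estimated as well (adjusted p = 0.420 with an estimated correlation). TXNIP, the brightest of them by mean log2 value, had 0.08, and -0.02 after quantile normalization.

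Of the markers of other cell types that an elutriated fraction can hold, 0 genes passed in limma over all probe sets or adjusted over the list alone. The median log2 change was -0.03 for 18 T cell markers (limma adjusted p = 0.676), 0.04 for 10 B cell and plasma cell markers (limma adjusted p = 0.425), 0.06 for 14 NK cell markers (limma adjusted p = 0.164), 0.03 for 17 granulocyte markers (limma adjusted p = 0.587) and 0.03 for 15 platelet and erythroid markers (limma adjusted p = 0.802, mean -0.00). An unadjusted p under 0.05 was found for 1 T cell, 1 B cell and 1 platelet or erythroid marker and for 0 NK cell and 0 granulocyte markers. Probe sets of these markers had signal in both arms, which alone does not tell whether other cells or the monocytes gave it. IL7R, a T cell marker, had 1125 ± 716 with vehicle and 1160 ± 653 with LTD4 (log2 change 0.08, and -0.05 at its other probe set). KLRB1, of NK cells, had 485 ± 296 and 534 ± 267, and HBB, of red cells, had 786 ± 232 and 866 ± 331. FCGR3B, of neutrophils, had 1136 ± 734 and 884 ± 387, higher in 2 of 4 donors. Its log2 change was -0.28, and 0.02 without replicate 2.

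RNA quality was read from the 3' and 5' control probe sets of GAPDH and ACTB, whose log2 ratio grows as RNA is degraded. For GAPDH the ratio was 0.25 ± 0.11 with vehicle and 0.12 ± 0.11 with LTD4, a difference of -0.13 (95% interval -0.46 to 0.20, exact two-sided sign-change permutation p = 0.25, higher in 1 of 4 donors). For ACTB it was 0.75 ± 0.15 and 0.66 ± 0.14, a difference of -0.09 (95% interval -0.28 to 0.09), lower in 4 of 4 donors, with an exact permutation p of 0.13, the smallest that 4 pairs allow, so this design cannot reach 0.05 by that test. The ribosomal protein and monocyte marker lists, with medians above 0 as deposited, thus stood beside a lower mean 3' to 5' ratio in the LTD4 arm.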

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

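The tests of handling stress and with an estimated correlation after quantile normalization or without a replicate were chosen after the result was seen, and the others before. In 86 groups of 4 samples examined, 2 held a sample far from its 3 others, where chance gives about 5%, or 4.30. In the vehicle samples DUSP6 had signals of 1917, 2038, 2091 and 3949, and on the log2 scale with 16 added the gap to the highest was 0.880 of the range. The highest was replicate 1, which was also the highest with LTD4 (5703). Its log2 change was 0.53, beside a mean of 0.45 over the donors. Also in the vehicle samples, the GAPDH 3' to 5' ratio had log2 values of 0.19, 0.20, 0.22 and 0.41, a gap of 0.866 of the range.

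Camera at its preset correlation placed the immediate early and feedback lists above other genes, calls lost at limma adjusted p = 0.169 with an estimated correlation, and adjusted over the list alone 15 of 30 and 7 of 22 members were higher and 2 and 0 lower. The data argue against a trend of bright probe sets as the cause: with quantile normalization the medians of the immediate early and feedback lists were 0.154 and 0.166, and each deposited median lay above 100% of 10000 random lists matched on signal. For handling stress, the upper 95% limit of the mean change of heat shock genes was 0.0199. It lay below 0.167, which is 50% of the immediate early list's mean change. This argues only against a stress that raises heat shock genes by that much. It cannot decide on handling stress that moves immediate early genes without heat shock genes within 30 min. Of the 35 splits of the 8 samples without the donor block, which leave the pairing aside, 1, the real one, gave the immediate early list a camera p as small (5.10e-10 against 7.04e-07 for the next), against 6 for the feedback list (real p 0.00134, lowest other 3.41e-05) and 4 for the calcium, NFAT and CREB list (real p 0.000832, lowest other 2.10e-05). An effect of LTD4 on immediate early genes is a hypothesis in line with these values, formed on the same data, and chance stays open because the splits that respect the pairing are too few to exclude it.

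Camera at its preset correlation also placed ribosomal proteins and monocyte markers above other genes (limma adjusted p = 0.437 and 0.169 with an estimated correlation), with 0 of 29 and 1 of 20 members past the threshold adjusted over the list alone, and here the trend of bright probe sets may account for the shift: with quantile normalization the medians were -0.0135 and 0.0193. The deposited ribosomal median lay at the 92.7th percentile of lists matched on signal and the monocyte marker median at the 97.8th, just outside the central 95%, while the brightest 10% of genes had a median of 0.05 as deposited and -0.01 with quantile normalization. RNA quality stays open, because the difference in the GAPDH 3' to 5' ratio, -0.131, has a 95% interval of -0.46 to 0.20, too wide to decide with 4 donors. Without the donor block 6 of 35 splits gave a camera p as small for ribosomal proteins (real p 1.16e-08, lowest other 2.20e-21) and 12 of 35 for monocyte markers (real p 0.00950, lowest other 5.82e-07). An action of LTD4 on these genes also stays open, untested apart from the arrays' brightness. Quantile normalization cannot separate it from a scaling difference, since giving all arrays 1 distribution also lessens a real rise shared by the brightest genes.

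For the 2 probe sets of FOSB and ATF3 that passed, 1 of the 8 splits that part every donor's pair, the real one, gave as many and the highest other gave 0; 8 splits are too few for a share under 0.05. The same holds for the lists that camera called, each of which had its smallest p in the real split of these 8: 2.46e-14 against 1.13e-08 for the immediate early list, 2.11e-06 against 0.0247 for feedback, 0.000749 against 0.0609 for calcium, NFAT and CREB, 4.91e-08 against 1.75e-05 for monocyte markers and 8.04e-18 against 5.60e-17 for ribosomal proteins. All 5 calls were lost with the correlation estimated (limma adjusted p = 0.437 for ribosomal proteins and 0.169 for each other list with an estimated correlation). Without the donor block the real split gave 0 probe sets in limma (915 at an unadjusted p under 0.05), so 35 of 35 splits gave as many. A count of 0 fixes that outcome in advance, so it cannot decide on chance. The highest other gave 270, a split that keeps each donor's samples together, which points to a structure of the samples by donor.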

How the results depend on the processing

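Estimating the correlation together with quantile normalization or with a replicate left out was added after the results were seen; the other alternatives were chosen before. The FOSB change kept its direction under all 15 alternatives run on it (log2 change 1.63 to 3.13) and its call under 8 of them; the ATF3 probe set kept its direction under all 14 run on it and its call under 5. Of all alternatives for named genes, 755 kept direction and side of the threshold, 9 gained and 16 lost a call, and 12 reversed; for gene lists the numbers were 223, 6, 35 and 21. The count of 2 probe sets and 1 gene past the threshold rests on few calls near it. It was 0 and 0 without the replicate block, with a pseudocount of 1, without a filter, with the lowest 60% not tested and without a trend in the variance prior, by limma in each case, with 915, 1998, 3119, 1509 and 2018 probe sets at an unadjusted p under 0.05. It was 4 and 2 with a pseudocount of 64 (FOSB and NR4A2), and 1 probe set with quantile normalization. With donor as a random block 2 genes passed, FOSB and, lower, TMEM120B, and 66.7% of 3 probe sets were higher against 100% in the fixed-block fit. An adjusted p under 0.1 gave 6 genes. Leaving out each replicate gave 0 to 13 probe sets and 0 to 9 genes; without replicate 1 there were 13 and 9, and without replicates 3 and 4 limma gave 0 (2308 and 1416 probe sets at an unadjusted p under 0.05). Apart from these counts, FOSB and the ATF3 probe set, dropping the block changed no call.

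With an estimated correlation camera lost the immediate early (median 0.19), feedback (0.18), calcium (0.020), ribosomal (0.14) and monocyte marker (0.13) lists. The estimates were 0.14, -0.036, -0.019, 0.80 and 0.084 in that order. For feedback and calcium they lay below the preset 0.01, so a higher correlation does not explain their loss. Fry did not call the immediate early (0.19), ribosomal (0.14) and monocyte (0.13) lists. Quantile normalization ended the calls of the ribosomal (-0.014) and monocyte marker (0.019) lists. At the preset correlation it kept those of the immediate early (0.15), feedback (0.17) and calcium (0.026) lists. With the correlation estimated too, these were lost, as they were in the deposited values. At the preset correlation camera kept the immediate early, feedback, calcium, ribosomal and monocyte lists with replicate 1, 2, 3 or 4 left out. In that order of replicates the medians were 0.23, 0.19, 0.18 and 0.17 for immediate early and 0.165, 0.25, 0.19 and 0.164 for feedback. For calcium they were -0.015, 0.054, 0.050 and 0.035. They were 0.097, 0.19, 0.15 and 0.12 for ribosomal and 0.098, 0.12, 0.16 and 0.11 for monocyte. With the correlation estimated, camera called none of these lists in the leave-outs, as with no replicate left out. Estimating the correlation also bases camera's p on the degrees of freedom from the samples, 3 in the full fit. How far this accounts for the losses was not tested. List tests pointed the other way, without a call except where stated, for coagulation with fry and without the replicate block (median -0.0056), with quantile normalization (-0.047) and without replicate 2 (-0.038) or 4 (-0.076 to 0.053 over the leave-outs); platelet and erythroid markers without a filter (0.029) and without replicate 1 (-0.032 to 0.068); B cell markers without replicate 1 (-0.016 to 0.14); chemokines (-0.027 to 0.099), interferon stimulated genes (-0.23 to 0.13, called lower without replicate 2 at the preset correlation only) and T cell markers (-0.10 to 0.033) without replicate 2; and heat shock genes without replicate 3 (-0.023 to 0.017). The adjusted p of the leukotriene list ran from 0.0279 to 0.554.

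Reversed genes, none of them called, were CD44 (-0.027), FN1 (-0.025), HSP90AA1 (-0.11), TXNIP (-0.022) and RPS16 (-0.045) with quantile normalization, and in the leave-outs TXNIP without replicate 1 (-0.033 to 0.12), ISG15 without replicate 2 (-0.20 to 0.33), HSP90AA1 without replicate 2 or 4 (-0.058 to 0.064), FCGR3B without replicate 2 (-0.51 to 0.024) and CYSLTR2 without replicate 3 or 4 (-0.25 to 0.089). TMEM120B and CYSLTR2 were not tested with the lowest 60% left out. Signal over background limits dim genes most: the log2 change of FOSB was 3.13 with a pseudocount of 1 and 1.63 with 64.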

Other observations

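The hypoxia and glycolysis list held 14 members below 0 and 7 above, and those given here were chosen after their values were seen. HK2, the hexokinase that starts glycolysis, had a log2 change of -0.40 (869 ± 136 to 652 ± 83.7), DDIT4, an inhibitor of mTORC1, -0.32, VEGFA -0.23 and ARRDC3 -0.20, each lower in 4 of 4 donors. LDHA had 0.14 (3692 ± 186 to 4074 ± 249), higher in 4 of 4 donors, ALDOA and PGK1 had 0.13 and 0.10, and EGLN3, an oxygen-sensing hydroxylase near background, had 0.25. None of these genes passed in limma over all probe sets or adjusted over the list alone. The list's median, -0.09, lay at the 0.16th percentile of 10000 random lists matched on signal. Its test passed with quantile normalization (limma adjusted p = 0.0290) and not with the correlation estimated as well, a test added after the results were seen (limma adjusted p = 0.420).

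Across all 32595 probe sets, 2532 were higher and 2528 lower with LTD4 in 4 of 4 donors, 15.5% in all against 12.5% by chance. Probe sets with an unadjusted p under 0.05 made up 6.56% against 5% by chance. Genes named among the 20 of smallest p were mostly higher, with TMEM120B the 1 exception.

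In the eicosanoid list, HPGDS, the haematopoietic prostaglandin D synthase, had a log2 change of 0.58 near background (20.8 ± 20.5 to 37.3 ± 24.5), and ALOX5AP, the activating protein of 5-lipoxygenase, had 0.24 (1193 ± 99.2 to 1433 ± 290). Both were higher in 4 of 4 donors and neither passed in limma over all probe sets or adjusted over the list alone. They were chosen after their values were seen, from a list with 13 members above 0 and 10 below.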
